A study of Mus musculus with 2 samples.

How the data were processed

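RNA was measured in 2 samples from the cerebellum of mice at postnatal day 7. The mice carry a transgene in which the Pcp2 promoter, active in Purkinje cells, drives the ribosomal protein L10a fused to green fluorescent protein. In translating ribosome affinity purification (TRAP), beads carrying antibodies against the fluorescent tag pull down tagged ribosomes together with the mRNAs bound to them. Per the labels' protocols, cerebella were pooled and homogenised in a buffer with cycloheximide. The cleared supernatant was incubated with the beads overnight. RNA was taken from the beads (the TRAP sample) and from what the beads left behind (the unbound sample). The number of animals pooled, and whether both RNA samples came from the same pool, are not given in the sources used here. Each fraction was hybridised to 1 Affymetrix whole-transcript mouse array with biotin-labelled cDNA, per the labels' protocols.

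The deposited table holds 1 log2 expression value per probe set and array, made by the authors with Affymetrix Power Tools, per the submitters' processing notes. The version, the background correction, the normalization and the summary method are not given in the sources used here. The log base is not stated either. Read as natural logs, the highest value would correspond to a signal of 847885, above the 65535 that a 16-bit scanner can record, so the values were taken as log2. The quartiles of the 2 columns differ, so the listed values are not quantile-normalized at the level of probe sets. The table has 22097 probe sets, of which 112 carry the same value on both arrays to the last decimal. It contains no detection calls and no scanner signals, so no background level is known for a probe set. The array number, not a read depth, limits the precision.

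Probe sets were named through the platform annotation. Of the 22097 probe sets, 20999 name 1 gene, 91 name several genes and were left out, and 1007 are unnamed here. Symbols were checked by Entrez identifier against the RefSeq genes of the GRCm38.p6 assembly, which matched 20959 of the probe sets that name 1 gene and supplied the gene types. No coordinates are given, because no genome build is named for the values. The named probe sets were averaged per gene, which gave 19503 genes, 18716 of them from a single probe set. A gene counted as above the floor when its value on at least 1 array exceeded 7.079, the median of all probe set values of both arrays together. This left 10524 genes. The difference is always the TRAP value minus the unbound value on the log2 scale. Values are used as deposited, with no further scaling.

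With 1 array per fraction there is no replicate, so no test was run, no p-value is given and no single gene has an error. Genes are described by a rule of size, a difference of at least 2-fold. A total of 29 gene lists (11 of cell type markers, the rest of pathways and RNA classes) was written before the data were examined. They hold 575 different genes, of which 479 have a value here. The remaining list genes were not analysed here. For each list with at least 5 members above the floor, the median difference is given with a 95% bootstrap interval over the members (10000 resamples). Its percentile is given among 10000 random lists of the same size, matched on the mean of both arrays in 20 bins. The interval covers the spread among the genes of a list, and both describe these 2 arrays only. Some genes stand on several lists. The genes named in the text are Pcp2 and Rpl10a, the 15 protein-coding genes with the largest difference in each direction, and up to 4 members per list, 2 from each end. In a list with 5 or fewer members above the floor, each may be named.

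Other settings, also chosen before the data were seen, were the subtraction of each array's median, quantile normalization of the arrays, removal of a loess trend of the difference on the mean level (span 0.3), no floor, a floor at the 75th percentile, a floor on the mean of both arrays, the brightest probe set per gene, thresholds of 1.5-fold and 4-fold, random lists matched on the unbound level or not matched, and genes held by 1 list only. Random lists matched on level and genomic span were added after the data had been seen. Subtracting the array medians moved the median difference of all genes by 0.33, because the TRAP array has the lower median. It went from 0.099 as deposited to 0.43, farther from 0. Quantile normalization gave 0.065 and removal of the loess trend 0.01, both nearer to 0. Scripts were tested on simulated data for these 19503 genes, with noise of 0.2 SD per array. That noise was a chosen value, the same at every level, because 1 array per fraction gives no estimate of it. The recovery checks the scripts and does not measure the precision of these arrays. Of 50 genes changed by 2 on the log2 scale in each direction, 50 higher and 49 lower ones were recovered as at least 2-fold apart. Of 50 changed by 1.5 in each direction, 47 higher and 48 lower ones were recovered. Of 100 simulated lists shifted by 0.5, 100 lay above the 97.5th percentile, and 8 of 100 unshifted lists lay outside the central 95%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6 were used.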

Results

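Ribosome-bound RNA of Pcp2-expressing cells was compared with the RNA left unbound in the same kind of preparation, using pooled mouse cerebella of postnatal day 7. At this age the cerebellum holds a small number of Purkinje cells beside dividing granule neuron progenitors, young granule neurons, interneurons and glia. The TRAP array had a median log2 value of 6.92 over all probe sets and the unbound array a median of 7.25. The Pearson r between the arrays was 0.94 across all probe sets and 0.78 across the 10524 genes above the floor. Neither probe sets nor genes are independent replicates. Each fraction was measured once, so every difference below is a difference between 2 arrays with no replicate check.

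The labels describe a purification of tagged ribosomes from Purkinje cells, and the comparison asks which transcripts were more abundant on those ribosomes than in the remaining RNA. Pcp2, the Purkinje cell gene whose promoter drives the tag, read 12.98 on the TRAP array and 11.65 on the unbound array, a 2.52-fold difference. Rpl10a, which encodes the tagged ribosomal protein, read 12.67 and 12.13, a 1.45-fold difference. Its 4 probe sets gave differences between 0.52 and 0.56, and probe sets for Rpl10a cannot separate the endogenous transcript, the transgene and near-identical gene copies.

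Of 10524 genes above the floor, 853 were at least 2-fold higher in TRAP and 1955 at least 2-fold higher in unbound. At 4-fold the counts were 78 and 457. The genes higher in TRAP made up 30.4% of those that differed at least 2-fold. This split depended on the scaling of the arrays: the share was 58.6% (1723 against 1215 genes) when each array's median was subtracted, 46.7% (1262 against 1439) after quantile normalization, and 36.9% (1003 against 1716) after a loess trend was removed.

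**Figure D1:**
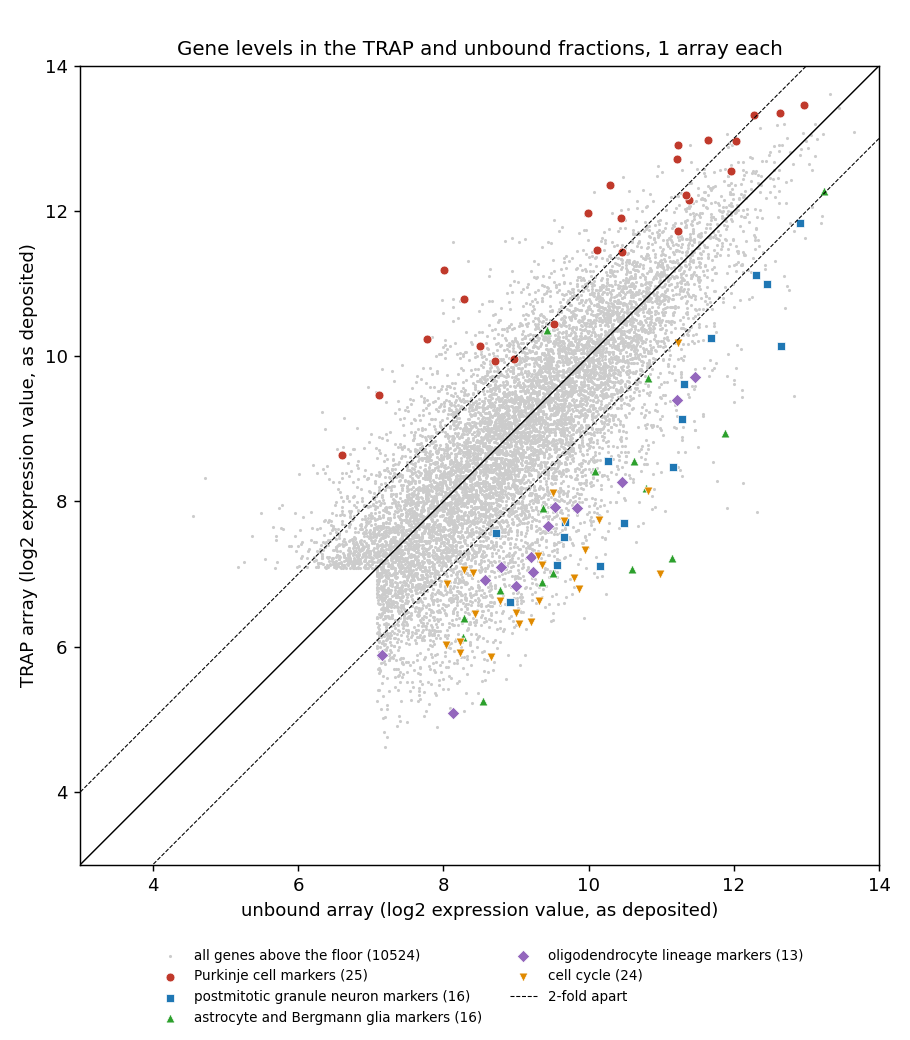
Log2 expression values of the 10524 genes above the floor on the unbound array (x axis) and the TRAP array (y axis), with 5 of the fixed lists coloured. The solid line marks equal values and the dashed lines a 2-fold difference; all 25 Purkinje cell markers lie above the solid line, and all 24 cell cycle genes lie below the lower dashed line.

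Among protein-coding genes, the 15 largest differences higher in TRAP ran from 2.57 to 3.60 on the log2 scale. Kalrn, a guanine nucleotide exchange factor of dendritic spines, read 11.58 in TRAP and 8.13 in unbound, a 10.9-fold difference. Gng13, a G protein gamma subunit on the Purkinje list, differed by 3.17 on the log2 scale. Itpka, an inositol trisphosphate kinase, was 7.83-fold higher (11.31 against 8.34). Prkcd, a protein kinase C isoform, was 6.29-fold higher (10.79 against 8.14). Smpx, encoding the small muscle protein, was 6.69-fold higher (11.59 against 8.85), and Nexn, encoding the actin-binding protein nexilin, 6.42-fold higher (11.63 against 8.95). Stac, which encodes an adaptor protein, was 6.88-fold higher, and Cox7a1, the muscle isoform of a cytochrome c oxidase subunit, 6.38-fold higher. The small heat shock protein genes Hspb3 and Hspb1 were 7.52-fold and 5.94-fold higher. The remaining genes were Sycp1, known from the meiotic synaptonemal complex, with 8.32 against 4.72, Gtsf2 with 7.80 against 4.55, the homeobox gene Dlx4, 1700028P14Rik and Lrrc73. Of the 128 genes named by rule, 40 had a value at or below the floor on 1 array, where the table gives no detection call and the fold is uncertain. In this group the unbound value of 5 of the 15 genes (Sycp1, Gtsf2, Hspb3, Dlx4 and 1700028P14Rik) lay there.

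The 15 largest differences higher in unbound ran from 3.19 to 4.46 in size. The mitochondrially encoded COX2, a cytochrome c oxidase subunit translated inside mitochondria, read 7.86 in TRAP and 12.32 in unbound, a 22.0-fold difference. Ccnb2, the mitotic cyclin B2, was 15.8-fold higher in unbound, and Ect2, required for cytokinesis, 11.7-fold higher. The astrocyte genes Gfap and Aqp4, encoding an intermediate filament protein and a water channel, were 15.1-fold and 11.6-fold higher in unbound. Ptprz1, a receptor phosphatase of glia, was 9.73-fold higher, and Gjc3, a connexin gene, 9.13-fold higher. Ttr, encoding the transthyretin that choroid plexus secretes, was 10.4-fold higher in unbound and still read 9.46 in TRAP. Bgn, a matrix proteoglycan gene, was 11.4-fold higher, and Cald1, encoding the actin-binding caldesmon, 9.51-fold higher. Lin7a, Arhgap29, Casp8, the interneuron transcription factor gene Tfap2b, and Rgs17 completed the group, with differences of 9.27-fold to 11.2-fold. The TRAP value of 9 of the 15 genes lay below the floor.

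All 25 measured Purkinje cell markers were higher in TRAP than in unbound, 15 of them at least 2-fold. Their median difference was 1.34 (95% bootstrap interval over members 0.93 to 1.68), a 2.52-fold difference, and it exceeded all 10000 matched random lists, whose central 95% ran from -0.27 to 0.38. Gng13 led the list with 11.18 against 8.01, and Slc1a6, the glutamate transporter of Purkinje dendrites, was 5.70-fold higher (10.79 against 8.28). The smallest differences belonged to Pcp4, a calmodulin regulator, with 0.49, and to Dab1, the adaptor of reelin signalling, with 0.50. No marker of this list changed sign under another scaling.

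Markers of granule cells were higher in unbound. For postmitotic granule neurons, each of the 16 markers above the floor was at least 2-fold higher in unbound, with a median of -2.05 (interval -2.45 to -1.47). Gabra6, the granule cell GABA-A receptor subunit, read 7.71 in TRAP and 10.49 in unbound, and Cbln3, a synaptic cerebellin gene, 7.11 and 10.15. Zic1 and Nhlh2, transcription factor genes, had the smallest differences at -1.07 and -1.16; with the array medians subtracted they were -0.74 and -0.83, and Rbfox3, a gene of mature neurons singled out after its value was seen, was -0.86, so that 13 of the 16 reached 2-fold. For granule neuron progenitors, 6 of 12 markers were at least 2-fold higher in unbound and the median was -1.24 (interval -1.83 to -0.48). Atoh1, the transcription factor gene that defines these progenitors, read 7.31 against 9.30, and Ccnd1, encoding cyclin D1, 7.68 against 10.03. Sfrp1 and Mycn, at -0.01 and -0.03, had nearly equal values on both arrays and turned positive when the array medians were subtracted, Mycn also after quantile normalization. The median of the postmitotic list lay below all 10000 matched random lists, and that of the progenitor list at the 0.02nd percentile.

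Cell cycle genes gave the lowest median of the lists with at least 5 members above the floor. All 24 measured genes were at least 2-fold higher in unbound, with a median of -2.27, below all 10000 random lists, whose central 95% ran from -0.69 to 0.21. After Ccnb2, the largest difference was that of Plk1, the mitotic polo-like kinase, with 6.79 against 9.87. Pcna, the replication clamp, and Cdc20, an activator of the anaphase-promoting complex, had the smallest at -1.05 and -1.19; with the array medians subtracted they were -0.72 and -0.85, and Aurka, a mitotic kinase gene singled out after its value was seen, was -0.89, all short of 2-fold.

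Inhibitory interneuron markers were also higher in unbound, with 6 of 7 at least 2-fold and a median of -1.42 (interval -2.68 to -1.27, percentile 1.53). Tfap2b and Kit led, at 9.29-fold and 6.40-fold. Pax2, the transcription factor gene of immature interneurons, differed by -1.27 and Nxph1 by -0.94. Pax2 fell short of 2-fold (-0.94) when the array medians were subtracted, and 5 of 7 markers reached it. For unipolar brush cells and excitatory nuclear neurons, 3 markers lay above the floor: Slc17a6 (a vesicular glutamate transporter gene), Meis2 and Eomes were 7.11-fold, 5.98-fold and 4.39-fold higher in unbound.

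Glial markers followed the same direction. Of 16 astrocyte and Bergmann glia markers, 14 were at least 2-fold higher in unbound and the median was -2.10 (interval -2.71 to -1.67). Fabp7, a fatty acid binding protein gene of radial glia, read 12.27 against 13.25. Hopx, a homeodomain gene, was the only member higher in TRAP, at 10.36 against 9.42. All 13 oligodendrocyte lineage markers above the floor were at least 2-fold higher in unbound, with a median of -1.83 (interval -2.16 to -1.69). Enpp6, a gene of newly forming oligodendrocytes, led with 5.08 against 8.13, followed by Sox10 with 7.03 against 9.24; Bcas1 and the myelin gene Mog differed by -1.61 and -1.26. With the array medians subtracted Mog was -0.93, and 12 of the 13 markers reached 2-fold. The medians of both glial lists lay below all 10000 matched random lists.

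Few markers of vascular and immune cells were measurable. Of 13 microglia markers on the table, 3 were above the floor, and Fcer1g and C1qb were 3.07-fold and 3.02-fold higher in unbound while Trem2 differed by -0.30 and turned positive with the array medians subtracted or after quantile normalization. The endothelial list had 1 gene above the floor, the glucose transporter gene Slc2a1, at -0.74. Of 6 mural and fibroblast markers, 4 were at least 2-fold higher in unbound, led by Dcn (5.48-fold) and Acta2 (4.15-fold), while the collagen genes Col1a1 and Col1a2 differed by 0.01 and -0.17, the latter positive under each of the 3 other scalings. The median was -1.83 (interval -2.26 to -0.08), but with no floor it was -0.27 over 12 genes and inside the range of random lists. Of the erythroid list, 2 genes had values and neither was above the floor.

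**Figure D2:**
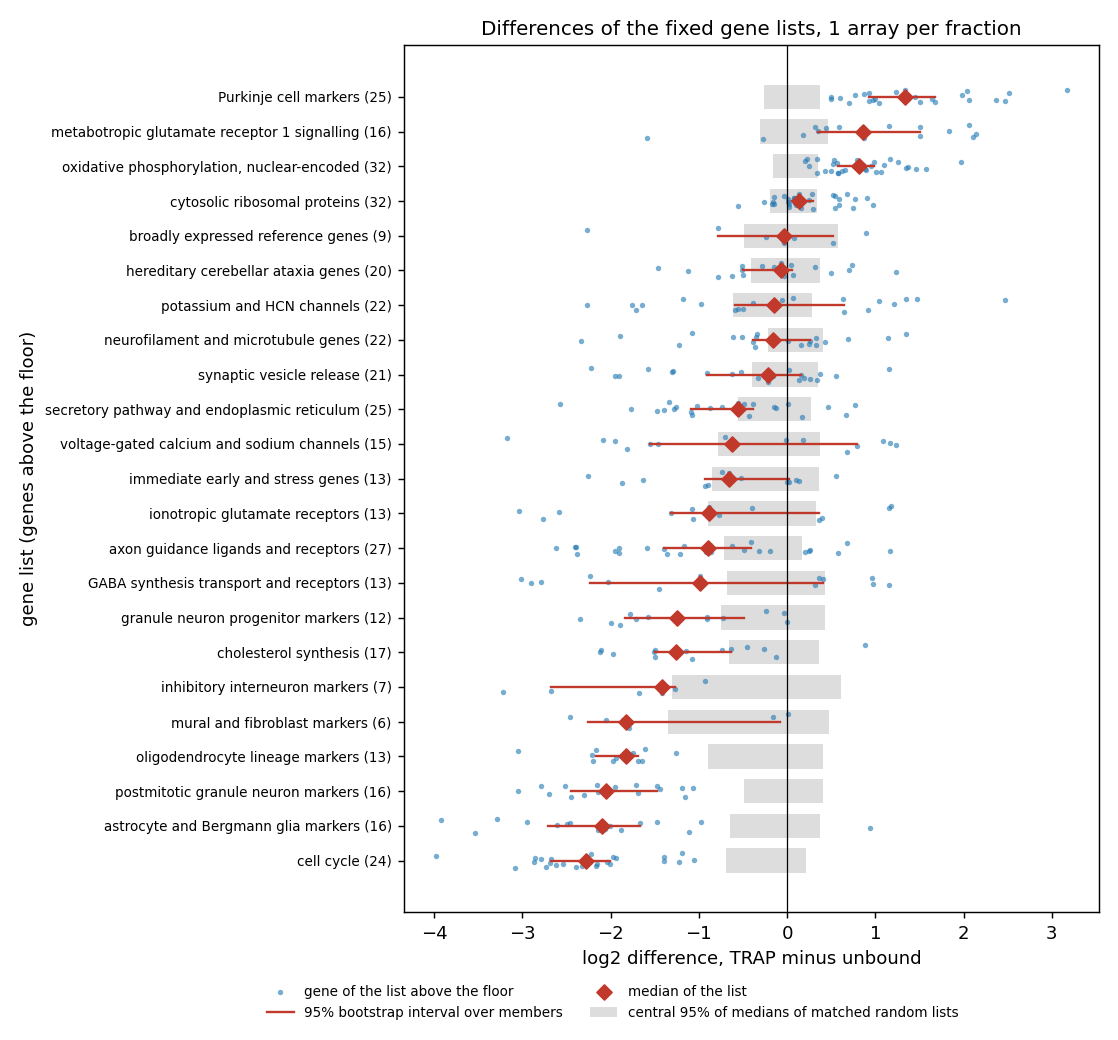
Log2 difference between the TRAP and unbound arrays (x axis) for each fixed list with at least 5 genes above the floor (y axis, number of genes in parentheses). Points are genes, diamonds list medians, red lines 95% bootstrap intervals over members, and grey bars the central 95% of the medians of matched random lists; the Purkinje list has the highest median (1.34) and the cell cycle list the lowest (-2.27).

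Genes of metabotropic glutamate receptor 1 signalling, the pathway of the parallel fibre synapse onto Purkinje cells, were mostly higher in TRAP. Of 16 members above the floor, 14 were higher in TRAP, 7 of them at least 2-fold, and the median was 0.86 (interval 0.36 to 1.51, percentile 99.99). Shank2, a postsynaptic scaffold gene, read 11.50 against 9.36, and Plcb3, a phospholipase C gene, 10.77 against 8.66. Homer2 read 8.37 in TRAP and 9.95 in unbound. Homer1 differed by -0.28 and turned positive with the array medians subtracted. The list shares 3 genes with the Purkinje list, and over the 13 members held by no other list the median was 0.59.

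Receptor and channel lists held genes at both ends. Among ionotropic glutamate receptor genes, 6 of 13 were at least 2-fold higher in unbound and 2 in TRAP. The AMPA receptor subunit gene Gria4 was 8.22-fold and the kainate receptor subunit gene Grik2 6.79-fold higher in unbound, while Grik1 and Grik4 were 2.26-fold and 2.23-fold higher in TRAP. The median of -0.89 (interval -1.31 to 0.37) lay at percentile 2.66. With the array medians subtracted 3 genes stayed at least 2-fold higher in unbound. Over the 7 genes above a floor at the 75th percentile the median was -1.07, at percentile 72.5 of random lists drawn from genes above that floor. A gene of low mean level passes that floor only through a large difference between the arrays, and so do the random genes matched to it. The percentile therefore does not show that the list's low position was lost. Among genes of GABA synthesis, transport and receptors, Gabrb1 and Gabra2 differed by -3.02 and -2.91, whereas Slc32a1, the vesicular GABA transporter, was 2.23-fold and Gad1, a GABA-synthesising enzyme, 1.96-fold higher in TRAP. The list's median was -0.99 (interval -2.23 to 0.41, percentile 0.17) but 0.39 over the 8 genes above that higher floor, and -0.33 with the floor on the mean of both arrays. For voltage-gated calcium and sodium channels the median was -0.62 (interval -1.56 to 0.80, percentile 6.74), and it was 0.73 over 8 genes with the higher floor. Cacna1g, a T-type calcium channel, and Cacna2d2 were 2.35-fold and 2.24-fold higher in TRAP, and Cacna2d1 and Cacna1c 9.01-fold and 4.24-fold higher in unbound. Potassium and HCN channels split evenly, with 5 of 22 at least 2-fold higher in each fraction and a median of -0.15 (interval -0.59 to 0.64) that turned positive under each of the 3 other scalings; Kcng4 was 5.52-fold and Kcnip1 2.78-fold higher in TRAP, and Kcnb2 and Kcnk9 4.81-fold and 3.38-fold higher in unbound. The TRAP values of Gria4, Grik2, Gabrb1, Gabra2, Cacna2d1, Cacna1c and Kcnb2 and the unbound value of Grik1 lay below the floor, so their folds are uncertain.

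Of 27 axon guidance genes above the floor, 12 were at least 2-fold higher in unbound and 1 in TRAP, with a median of -0.90 (interval -1.40 to -0.41, percentile 0.29). The random lists here, like those of the receptor and channel lists, were not matched on genomic span. Differences fell with span across genes (Spearman rho -0.25), so a part played by span stays open for these lists and was not tested. Chl1, a cell adhesion molecule, and Plxna2, a semaphorin receptor, were 6.14-fold and 5.30-fold higher in unbound. Sema7a was 2.24-fold higher in TRAP and Sema3a 1.60-fold. Over the 7 genes above the higher floor the median was -1.90. The synaptic vesicle list had a median of -0.21 (percentile 14.6), or 0.12 with the array medians subtracted: the active zone gene Pclo and the vesicle protein gene Sv2b were 4.67-fold and 3.85-fold higher in unbound, and Vamp1 was 1.47-fold higher in TRAP. The neurofilament and microtubule list had a median of -0.16 (percentile 4.99), or 0.17 with the array medians subtracted. Nefh and Nefm, neurofilament genes of large axons, were 2.54-fold and 2.20-fold higher in TRAP, while Dcx, a gene of migrating neurons, and Map2 were 5.04-fold and 3.72-fold higher in unbound. Hereditary cerebellar ataxia genes had a median of -0.07 (interval -0.50 to 0.05, percentile 38.2), with Cacna1g and Afg3l2 at the upper end (1.23 and 0.74) and Elovl5 and Elovl4 at the lower (-1.46 and -1.12). The sign of that median was positive, 0.26, with the array medians subtracted.

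Genes of energy and lipid metabolism separated. All 32 measured nuclear-encoded oxidative phosphorylation genes were higher in TRAP, 10 of them at least 2-fold, with a median of 0.81 (interval 0.58 to 0.98) above all 10000 random lists. With the array medians subtracted 18 were at least 2-fold higher and the median was 1.14. Ndufb8 and Ndufb5, subunits of complex I, were 3.93-fold and 2.98-fold higher, and Atp5b and Uqcrc2 had the smallest differences at 0.20 and 0.22. In contrast, 11 of 17 cholesterol synthesis genes were at least 2-fold higher in unbound and the median was -1.25 (percentile 0.01), where the central 95% of random lists ran from -0.65 to 0.36. With the array medians subtracted 6 genes stayed at least 2-fold higher in unbound. Fdft1, squalene synthase, read 8.67 against 10.79 and Cyp51 6.24 against 8.35. Pmvk was higher in TRAP (10.46 against 9.58), and Fdps, at -0.13, turned positive under each of the other 3 scalings. Among genes of the secretory pathway and endoplasmic reticulum, 10 of 25 were at least 2-fold higher in unbound and none in TRAP, with a median of -0.55 (interval -1.08 to -0.38) at percentile 2.54. With the array medians subtracted the median was -0.22, with 5 genes at least 2-fold higher in unbound and 2 in TRAP. Stt3a, an oligosaccharyltransferase subunit, was 5.95-fold and Ssr3 3.42-fold higher in unbound, while Sec61b and Spcs1 were 1.71-fold and 1.59-fold higher in TRAP.

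Cytosolic ribosomal protein genes differed little, with a median of 0.13 (interval 0.05 to 0.30, percentile 66.2) and none of 32 at least 2-fold apart in the deposited scaling. With the array medians subtracted the median was 0.46 and 5 were at least 2-fold higher in TRAP. Rps19 and Rpl27 were 1.97-fold and 1.88-fold higher in TRAP, Rplp0 was 1.47-fold higher in unbound, and Rpl4, at -0.26, turned positive with the array medians subtracted. Many of these genes have near-identical copies that can share probes. Broadly expressed reference genes had a median of -0.04 (interval -0.78 to 0.53, percentile 35.4), or 0.29 with the array medians subtracted, with B2m, a gene of antigen presentation, 4.79-fold higher in unbound, Tbp at -0.78, and Pgk1 and Sdha at 0.89 and 0.53. Immediate early and stress genes had a median of -0.65 (interval -0.93 to 0.02, percentile 7.57), with Dusp1 and Btg2 4.76-fold and 3.66-fold higher in unbound and Dnajb1 and Ddit3 at 0.55 and 0.14. Over the same 13 genes the median was -0.32 with the array medians subtracted and -0.41 after quantile normalization. It was -0.11 over 19 genes with no floor and -0.01 over the 5 genes above the higher floor.

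Of 13 mitochondrially encoded mRNAs, COX2 was the 1 with a value here. Of the largely nuclear long noncoding RNAs, 4 were above the floor, with a median of -1.56 and 2 at least 2-fold higher in unbound. Malat1, which is retained in the nucleus, read 7.91 in TRAP and 11.91 in unbound, a 16.0-fold difference, and Meg3 read 8.07 and 10.88. Airn and Snhg11 differed by -0.32 and -0.27, and both turned positive with the array medians subtracted or after quantile normalization.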

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

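The 2 probe sets singled out here were chosen only after the result was seen. Probe sets without a gene name entered no comparison, and some of them were brighter in TRAP than in the unbound fraction. The unbound fraction is the comparison sample and no control for RNA that binds to the beads without the tag. The 2 samples include no pull-down from mice without the tag. Of 538 such probe sets above the floor, 40 were at least 2-fold higher in TRAP and 153 at least 2-fold higher in unbound. The largest was probe set 10582549, with 11.60 in TRAP and 5.49 in unbound, a log2 difference of 6.12, beyond the 3.60 of any named gene. Probe set 10464754 followed with 2.70. Neither was named here and neither has a replicate.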

How the results depend on the processing

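No setting in this part was chosen only after the result was seen. None of them turned the sign of a list median whose interval lay on 1 side of 0, while the GABA, calcium and sodium channel, potassium channel, ataxia, vesicle, neurofilament and reference medians, whose intervals include 0, changed sign under at least 1. The list medians stayed within their bootstrap interval in 171 comparisons with another setting and left it in 10. For a list that shares no gene, the setting of genes held by 1 list only repeats the main value. All 512 comparisons for named genes moved by less than 1.5-fold, but many of them could not have moved more. Subtracting the array medians adds the same 0.33 to every gene. The brightest probe set changes nothing for a gene with 1 probe set. Of 94 named genes at least 2-fold apart, 87 stayed so under the 3 other scalings and with the brightest probe set, and 9 of 128 named genes changed sign under at least 1 of these. The count of genes at least 2-fold higher in TRAP was 853. It was 1723 with the array medians subtracted, 1983 at 1.5-fold and 78 at 4-fold. The count higher in unbound was 1955. It was 1215 with the array medians subtracted, 986 with the floor at the 75th percentile (which left 5720 genes), 3252 at 1.5-fold and 457 at 4-fold. All 853 genes higher in TRAP and 1215 of the 1955 higher in unbound were called with the array medians subtracted too. That setting adds the same 0.33 to every gene, which moved the median of the interneuron list to -1.09. The median of the oligodendrocyte list was -1.55 there, over 12 genes above the floor in place of 13. Quantile normalization gave -1.17 for the interneuron list, and the cause was not tested. Without a floor the mural and fibroblast median was -0.27, at percentile 18.7. The ionotropic glutamate receptor list lay below the 2.5th percentile with 8 other settings, at 2.66 as reported and at 72.5 with the floor at the 75th percentile, where its median was -1.07, and the secretory pathway list crossed that bound with 3 of them. The median of -1.07 is farther from 0 than the -0.89 reported, so the 72.5 is no reversal. With that floor, matched random genes of low mean level also pass only through large differences, so percentiles there are uncertain. The GABA list went from percentile 0.17 to 87.1 with the floor at the 75th percentile and 14.4 with the floor on the mean. The calcium and sodium channel list went from 6.74 to 99.1 with the floor at the 75th percentile and 1.44 with no floor. The ribosomal protein list lay at percentile 97.8 among random lists matched on the unbound level. With 1 array per fraction, no array could be left out and no paired analysis was possible.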

Other observations

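The tests on an intensity trend, on genomic span, on short mRNAs, on Tmem genes against each list and on the differences of muscle mRNAs were chosen only after the result was seen, as were the groups by gene type, the muscle-associated group and the single genes named in this part. Some structural RNAs were higher in unbound. Rmrp, the RNA of the RNase MRP ribonucleoprotein, read 8.25 in TRAP and 12.13 in unbound, and Rpph1, the RNase P RNA, 9.72 and 11.91. The Y RNAs Rny1 and Rny3 read 8.54 against 11.71 and 10.92 against 12.76. The other types differed among themselves. Of 125 genes typed as long noncoding RNA above the floor, 25 were at least 2-fold higher in TRAP and 7 in unbound, with a median of 0.34 (95% bootstrap interval 0.24 to 0.50), and 0.50 after the loess trend was removed. A730036I17Rik (9.51 against 7.07) and Gm10190 (9.68 against 7.69) led these. The 28 genes typed as microRNA above the floor had a median of 0.47 with none at least 2-fold higher in TRAP and 2 in unbound. For 10 snoRNA genes the median was -0.83 (interval -1.37 to 0.33), with 1 at least 2-fold higher in TRAP and 3 in unbound.

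The oxidative phosphorylation genes stood as a group above the other metabolic lists (median 0.81). Removing the intensity-dependent trend left the median at 0.74, above all 10000 random lists, which argues against that trend as the whole cause. Differences fell with genomic span across 10521 genes (Spearman rho -0.25, across genes, which are not independent), yet random lists matched on level and span had a median of 0.17 (central 95% -0.09 to 0.49), below the observed value. Ribosomal protein genes, whose mRNAs are short, had a median of 0.13 (0.02 after the trend was removed), and subtracting the array medians moves both lists alike. This class of short mRNAs was thus not raised as the oxidative phosphorylation genes were. It is 1 class, with near-identical copies that can share probes, and mRNA length was not measured. A preference for short mRNAs therefore stays open. A difference between Purkinje cells and the cells around them also stays open and was not tested.

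Cholesterol synthesis genes (median -1.25) and, less so, secretory pathway genes (median -0.55, at the edge of the central 95% of random lists) were lower in TRAP. After the intensity trend was removed the cholesterol median was -1.09, below the central 95% of random lists (-0.54 to 0.46), which argues against that trend as the whole cause. Loss of mRNAs translated at the endoplasmic reticulum was a candidate explanation. The 137 Tmem genes above the floor, which encode membrane proteins, had a median of -0.28 (interval -0.43 to 0.05). That lay wholly above the cholesterol list's interval (-1.499 to -0.635), so this class was not lowered by that size. Other lists of membrane or secreted proteins were split. Axon guidance ligands and receptors had a median of -0.90 (interval -1.40 to -0.41), overlapping the cholesterol list's interval. Potassium and HCN channels had a median of -0.15. Such a loss therefore stays open for the cholesterol list. For the secretory list the median was -0.48 after the trend was removed (interval -0.94 to -0.25, percentile 1.74). That interval lay below the random median of -0.01. The rule of this test also asked for a place below the 2.5th percentile as deposited, where the list stood at 2.54. The test therefore did not decide on the trend. The list still lay near the edge of the central 95% of random lists (-0.44 to 0.39). A loss of mRNAs translated at the endoplasmic reticulum also stays open for the secretory list, because its interval as deposited (-1.08 to -0.38) overlaps that of the Tmem genes. A difference between Purkinje cells and the cells of the unbound fraction stays open for both lists and was not tested.

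The muscle-associated genes Smpx, Nexn, Hspb3 and Cox7a1 had differences between 2.67 and 2.91. Muscle tissue in the sample would be expected to raise its abundant mRNAs too. The median difference of 30 such mRNAs was 0.33 (quartiles 0.11 and 0.46) and 28 of 30 were below 1. This does not decide the question, because only 6 of the 30 lay above the floor on either array. The 4 genes were also picked for their large differences. The 6 above the floor had a median of 0.51, with Tnnt1 (2.14) and Cox6a2 (1.65) highest, then Acta1 (0.51), Tnnc1 (0.51), Actc1 (0.49) and Tnnt3 (0.36). A test set before its result, on the share above the floor in TRAP, did not decide (6 of 30, exact 95% interval 7.7% to 38.6%), and a later comparison of levels was set aside, because levels of different probe sets are not comparable. Muscle tissue and expression in the tagged cells both stay open, and the latter was not tested.

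The transgene could raise genes that lie next to Pcp2 if they came along in the construct. Within 150 kb of Pcp2, 14 neighbouring genes had values and 7 lay above the floor. Their median difference was 0.17 (percentile 76.1), with none at least 2-fold apart as deposited. Trappc5 (11.68 against 10.69, a difference of 0.99) was the highest, followed by Stxbp2 (0.68). Subtracting the array medians adds 0.33 to every gene, which takes both past 2-fold. The value lies between what passenger expression and its absence predict, and too few genes were above the floor to decide.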
